A study of Homo sapiens with 16 samples.

How the data were processed

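PC9 cells without gene editing were profiled with vehicle (DMSO) or osimertinib by genome binding assays for KDM1A, H3K4me1, H3K4me3 and H3K9me3, with 1 library per target and treatment and 8 libraries analysed. The 6 RNA samples, from control cells and cells with a PKM2 guide, and the 2 IgG samples were not analysed here. The type of binding assay and the dose and time of osimertinib in it are not given in the sources used here. Groups were taken from the sample titles and treatments.

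Each library was deposited as a table of annotated regions. Reads were placed on the human genome GRCh38 (hg38), per the submitters' processing notes, which name Bowtie2 2.3.4, HISAT2 and featureCounts without saying which assay each served. The peak caller, its threshold, the control, any blacklist and the annotation tool are not given in the sources used here. The deposited signal is a coverage-like height per region that is never negative, and whether it is scaled to depth or to IgG is not stated. It was therefore used only to rank, describe and filter regions within a list. Another deposited column repeats the width 2000 a number of times per region, per the file headers and values, and a further one gives the other unit used, the signed distance in bp to the nearest transcript start. Every region is 2 kb wide, no regions overlap within a list, and lists were not pooled. Region positions, annotation classes and gene assignments are those of the authors. Read depth is unknown, so precision rests on region numbers alone.

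Gene IDs were matched to symbols for 99.3% to 99.8% of regions per list, which also restored between 0 and 9 gene names per list that had turned into dates. A promoter region was one the authors annotated within 3 kb of a transcription start. For each target the analysis counted regions, promoter genes in the vehicle list only, the osimertinib list only or both, and regions of a list that overlapped the other by at least 1 bp. With 1 library per group no test between treatments was made and no p-value was computed. Shares have Clopper-Pearson 95% intervals, ratios of counts have intervals from the exact binomial distribution, and differences of shares have Newcombe intervals. All cover counting error only. No chromosome lengths were used here, so chance overlap came from 200 rotations of the regions of a list along the span of each chromosome covered by the 8 lists.

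Before the data were examined, 20 gene lists were fixed for lipid, carbon and EGFR-MAPK pathways, cell cycle, apoptosis, lineages, other cell types, lysine methylation and stress defence, along with all gene symbols that begin with ZNF. The score of a list was the share of its genes with a promoter region in the osimertinib list only minus the share in the vehicle list only. Its percentile was taken among 10000 random lists of the same size, matched on the mean signal percentile over both libraries in 5 strata, and lists with fewer than 5 genes got counts only. Signal percentiles took the place of the planned enrichment values. On simulated data with 5000 genes, 7.5% of 200 random lists of 25 genes lay beyond the 5th or 95th percentile. Of lists with 12 planted losses, 97.0% lay at or under the 5th. The simulated strata were drawn independently of the score, so this does not check the matching on signal. Overlaps between the vehicle and osimertinib lists of each target were checked against bedtools 2.31.1, and planted overlaps were recovered in simulated regions.

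Genes were named by a rule. It took the 16 focus genes for every target. It also took up to 4 genes per list with a promoter region in 1 list only and the highest signal there, for the lists of lipid, glycolysis, EGFR-MAPK, lysine methylation and lineage genes and those at or beyond the 5th or 95th percentile. Finally it took the 5 promoter genes of each target with the highest signal in the osimertinib list only and the 5 in the vehicle list only, leaving out genes without a symbol. Other genes named from counts of 5 or fewer, the regions inside KDM1A, the genes on chromosome 5 and those set beside them were chosen after their values were seen. Some genes that this rule names are not reported here.

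Alternatives were merging regions within 1 kb, leaving out chromosome Y, requiring an overlap of 1000 bp, counting regions within 1 kb as shared, equal numbers of the strongest regions, promoters within 1 kb, any assigned region, and random lists without matching. Added after seeing the data were runs without the first 50 Mb of chromosome 5 and without regions on RefSeq pseudogenes (GRCh38.p14), the rotations, the alternatives for KDM1A genes against the marks, and gene lists in which a gene whose promoter region lay within 1 kb of a region of the other list counted as in both. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Log2 values are given to 2 decimals and other values to 3 significant digits.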

Results

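The series asks how PKM2, an isoform of pyruvate kinase made from the PKM gene, and the synthesis of fatty acids bear on how lung cancer cells respond to osimertinib, an inhibitor of mutant EGFR. PC9 is an established human non-small cell lung cancer line with an activating EGFR mutation. The libraries analysed came from unedited PC9 cells given vehicle (DMSO) or osimertinib, with 1 library per target and treatment. The targets were KDM1A (LSD1), an enzyme that removes methyl groups from histone H3, and the histone marks H3K4me1, H3K4me3 and H3K9me3. Each library was represented by a list of 2 kb regions, with 4731 regions for KDM1A with vehicle and 8882 with osimertinib. H3K4me1 had 9761 and 6515 regions, H3K4me3 had 11621 and 13285, and H3K9me3 had 2749 and 2073, in the same order. The 6 RNA samples and 2 IgG samples of the series were not analysed here. No difference between vehicle and osimertinib has a replicate check, and the intervals given are 95% exact intervals that cover counting error only. Positions refer to GRCh38, and a rank is the place of a region by signal within its own list.

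**Figure D1:**
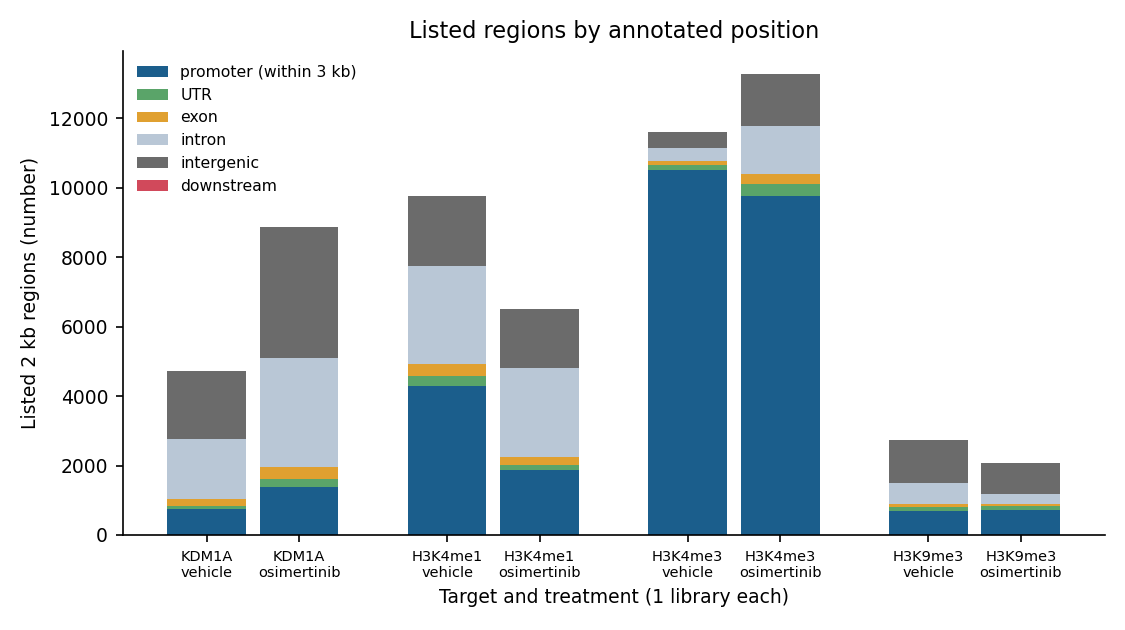
Number of listed 2 kb regions (vertical axis) in each of the 8 libraries (horizontal axis, 1 library per target and treatment), stacked by annotated position. The H3K4me3 bars are mostly promoter regions, 90.5% with vehicle and 73.5% with osimertinib, and the KDM1A bars are mostly intron and intergenic regions.

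H3K4me3, a mark of active gene starts, was listed at the promoter of ACACA with vehicle and not with osimertinib. A promoter region assigned to SCD was listed with vehicle only, though an osimertinib region assigned to another gene lay close by. ACACA codes for acetyl-CoA carboxylase and SCD for stearoyl-CoA desaturase, enzymes of fatty acid synthesis. FASN (fatty acid synthase), ACLY (ATP citrate lyase), the elongase gene ELOVL6 and SREBF1, a transcription factor gene of lipid synthesis, had a promoter region in both lists. Promoters of EGFR, PKM, MYC, CCND1, GAPDH and KDM1A were also in both lists, as were those of DUSP6 (a phosphatase that limits ERK), BCL2L11 (a promoter of apoptosis) and CPT1A (the carnitine step of fatty acid oxidation). ACSL1, an acyl-CoA synthetase gene, had no H3K4me3 promoter region in either list. In all, 8096 genes had a promoter region with vehicle and 7124 with osimertinib, a log2 ratio of -0.18 (-0.23 to -0.14), and 5401 genes were in both.

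The SCD region with vehicle (chromosome 10, 100347199 to 100349198) began 75 bp from the annotated start, within the gene, and ranked 899 of 11621. With osimertinib a region assigned to another gene, ranked 12873 of 13285, lay 218 bp from that vehicle region, on the other side of the start. The absence of SCD from the osimertinib list thus rests partly on gene assignment. The ACACA region (chromosome 17, 37357735 to 37359734) ranked 5579. Of the 28 genes in the fatty acid synthesis list, 20 had an H3K4me3 promoter region in either list: 7 in the vehicle list only, 1 in the osimertinib list only and 12 in both. SCD, SCD5, ACACA and ACSS2 were the strongest of those with vehicle only, and the single gene with osimertinib only was HACD3, named after its value was seen. The list's share with osimertinib only minus vehicle only was -30.0%, at percentile 10 of 10000 random gene lists matched on signal. Cholesterol synthesis genes numbered 7 with vehicle only, 3 with osimertinib only and 9 in both, at percentile 20.8. INSIG1, HMGCS1 and MSMO1, a regulator and 2 enzymes of sterol synthesis, were among those listed with vehicle only. For fatty acid oxidation, ETFDH, ACADM and ECI2 were in the vehicle list only, HADH was in the osimertinib list only and 9 genes were in both, at percentile 35.7.

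Genes that report on EGFR and MAPK signalling mostly had an H3K4me3 promoter region in both lists. Of 20 such genes with a region in either list, 16 were in both, EGR1 and EPHA4 in the vehicle list only, and SPRY4 and ETV5 in the osimertinib list only, at percentile 64.1. Glycolysis genes had 13 of 18 in both, with HK1, PFKFB3 and PGAM1 in the vehicle list only and ENO2 and PFKM in the osimertinib list only, at percentile 53.0. PFKM was named after its value was seen, and a region of the other list lay within 1 kb of the regions of PGAM1 and ENO2. Among 34 lysine methylation genes, 25 were in both, 6 in the vehicle list only, among them KDM4A and HDAC1, and 3 in the osimertinib list only, among them EHMT2, at percentile 39.1.

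The list of TCA cycle genes stood lowest among the H3K4me3 lists, at percentile 1.29. Of its 15 genes with a promoter region, 7 were in the vehicle list only, 0 in the osimertinib list only and 8 in both. PC, SUCLA2, FH and IDH1 (pyruvate carboxylase, a succinyl-CoA ligase subunit, fumarate hydratase and isocitrate dehydrogenase) were the strongest of the 7. None of the 7 had a region of the osimertinib list within 1 kb, and the list stood at percentile 0.845 when genes with such a region were counted as in both. Epithelial genes stood at percentile 4.47, with JUP, MUC1 and CLDN3 in the vehicle list only and 17 of 20 genes in both, and at percentile 36.5 when the random lists were not matched on signal. JUP and MUC1 had an osimertinib region within 1 kb, and the list stood at percentile 37.4 when such genes were counted as in both. Genes named ZNF, most of them zinc finger genes, stood at percentile 96.2, with 54 in the vehicle list only, 46 in the osimertinib list only and 195 in both, and at percentile 85.9 with equal numbers of regions. ZNF687 and ZNF639 were among the strongest with vehicle only. Over the 4 targets, 33 lists had enough genes for a percentile, and 3 lay at or beyond the 5th or 95th, where 3.3 would by chance.

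Cell cycle genes had 8 of 25 H3K4me3 promoters in the vehicle list only and 2 in the osimertinib list only, at percentile 6.78. The apoptosis list had 6 and 3 of 22 (percentile 35.9), the pentose phosphate and serine list 4 and 2 of 12 (percentile 39.0), and the mesenchymal list 3 and 0 of 10 (percentile 17.4). The receptor tyrosine kinase list had FGFR3 in the vehicle list only and FGFR1 in the osimertinib list only, of 9 (percentile 61.7). Interferon and antigen presentation genes had 2 and 1 of 13 (percentile 48.4), and NFE2L2 and ferroptosis genes 1 and 0 of 17 (percentile 46.4). Of the lung lineage genes, AGER was in the vehicle list only, with an osimertinib region of another gene overlapping its own, and 4 were in both (percentile 25.8). KRT15 of the squamous list and ENO2, which is also in the neuroendocrine list, were in the osimertinib list only. Among the leukocyte markers, NKG7 was in the vehicle list only and ITGAM in the osimertinib list only, and of 16 fibroblast and endothelial markers 0 had an H3K4me3 promoter region.

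**Figure D2:**
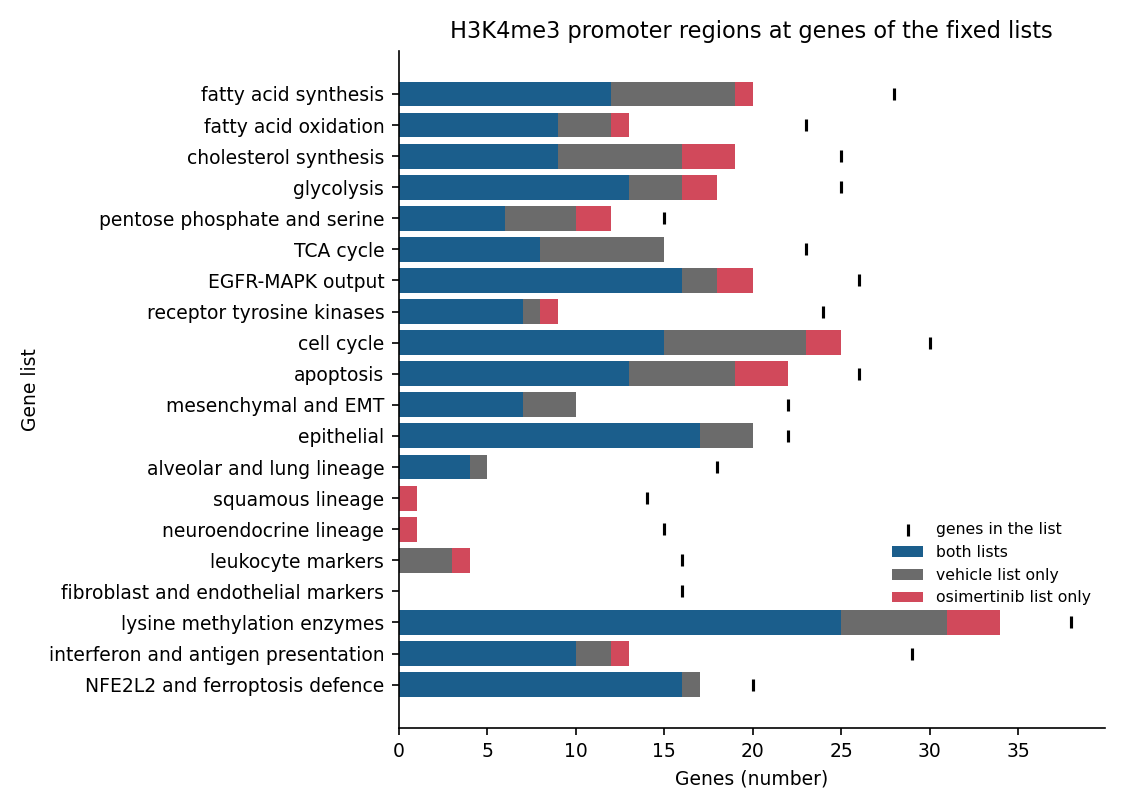
Number of genes (horizontal axis) of each gene list (vertical axis) with an H3K4me3 promoter region in both lists, in the vehicle list only or in the osimertinib list only, with 1 library per treatment. Black marks give the number of genes in the list, and the TCA cycle list has 7 genes with vehicle only and 0 with osimertinib only.

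The H3K4me3 promoters with the highest signal that were in the osimertinib list only belonged to RPS2, HSPA1B, HIST1H2AD, SNORD12 and MIR6805, and those in the vehicle list only to HNRNPUL2-BSCL2, LINC01962, FTL, JUNB and RPL28. FTL codes for ferritin light chain and JUNB for an AP-1 transcription factor, and their regions ranked 121 and 139 of 11621. Most of these names do not stand for a clear presence or absence. The RPL28 and MIR6805 regions overlapped each other, those of HIST1H2AD, SNORD12 and FTL overlapped a region of the other list assigned to another gene, and that of HNRNPUL2-BSCL2 lay 485 bp from one. The JUNB region lay 1290 bp from an osimertinib region ranked 50 and assigned to HOOK2, that of HSPA1B 1336 bp from a vehicle region of the same gene, and that of LINC01962 2187 bp from an osimertinib region. The regions themselves overlapped for 59.6% of the vehicle list (58.7 to 60.5) and 52.0% of the osimertinib list (51.2 to 52.9), where 200 rotations of the regions along their chromosomes gave a mean of 3.19% and 2.75%. Promoter regions made up 90.5% of the vehicle list (89.9 to 91.0) and 73.5% of the osimertinib list (72.7 to 74.2). Regions assigned to EGFR numbered 3 with vehicle and 13 with osimertinib, and those assigned to MYC 1 and 6.

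**Figure D3:**
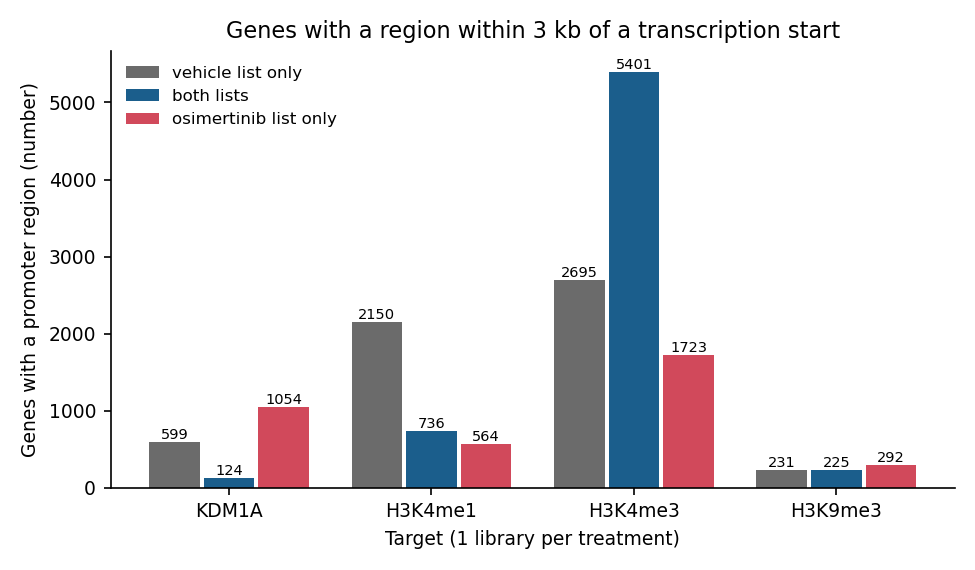
Number of genes (vertical axis) with a region within 3 kb of a transcription start in the vehicle list only, both lists or the osimertinib list only, for each target (horizontal axis, 1 library per treatment). For H3K4me3 5401 genes were in both lists, and for KDM1A 124.

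H3K4me1, a mark of enhancers and promoter flanks, was listed at the promoters of the glycolysis genes SLC16A3, ENO1, GAPDH and HK2 with vehicle and not with osimertinib, ranked from 2542 to 3341 of 9761. PKM was also in the vehicle list only, but ranked 9042, beyond the 6515 regions of the osimertinib list. CPT1A was in the vehicle list only too, as was MYC, which had 2 regions outside its promoter with osimertinib. EGFR and SREBF1 had H3K4me1 promoter regions in both lists, and all regions assigned to EGFR numbered 19 with vehicle and 33 with osimertinib. ACSL1 had a promoter region with osimertinib only, and SCD had 2 regions outside its promoter with vehicle only. ACLY, ACACA, FASN, ELOVL6, KDM1A, DUSP6, CCND1 and BCL2L11 had no H3K4me1 region in either list. Promoter regions were listed for 2886 genes with vehicle and 1300 with osimertinib, a log2 ratio of -1.15 (-1.25 to -1.06), with 736 genes in both.

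Glycolysis genes had 7 H3K4me1 promoters in the vehicle list only, 0 in the osimertinib list only and 2 in both, at percentile 10.4 of matched random lists. Among fatty acid oxidation genes, CPT1A and ACADVL had a promoter region with vehicle only. In the fatty acid synthesis list ELOVL1 was in the vehicle list only, ACSL1 in the osimertinib list only and 3 genes in both (percentile 81.6). Among the cholesterol genes, TM7SF2 and SREBF2 were in the vehicle list only and FDFT1 in the osimertinib list only. EGFR-MAPK genes had LIF, FOSL1, MYC and DUSP4 in the vehicle list only and 6 genes in both (percentile 25.5). RCOR1 and RCOR2, partners of KDM1A, and KDM2B and TRIM28 were in the vehicle list only, and the other lysine methylation gene with a region, KDM2A, was in both (percentile 18.8). The lineage genes SCGB1A1, CAV1, PKP1, KRT6B and POU2F3 were in the vehicle list only and KRT5 in the osimertinib list only. Of the fibroblast and endothelial markers PDGFRB was in the vehicle list only, and 0 of the 16 leukocyte markers had an H3K4me1 promoter region. The other lists with a percentile lay between percentile 25.6, for interferon and antigen presentation genes (4 with vehicle only, 0 with osimertinib only), and percentile 83.9, for cell cycle genes (2 and 1). The highest signals were at KCTD2, LINC00112, PACS1, LINC01173 and PTGFRN among promoters with osimertinib only, and at ARRB1, SSH3, MIR4669, EXOC3L4 and CHKA among those with vehicle only. The regions of SSH3 and LINC00112 lay within 1 kb of a region of the other list, and those of CHKA, MIR4669 and PTGFRN within 3 kb.

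H3K4me1 regions overlapped for 26.6% of the vehicle list (25.7 to 27.5) and 39.7% of the osimertinib list (38.5 to 40.9), where rotation gave means of 1.15% and 1.66%. Promoters made up 44.0% of the vehicle regions (43.0 to 45.0) and 28.7% of the osimertinib regions (27.6 to 29.8), and introns 28.8% and 39.3%. When the same number of strongest regions was taken from both lists, the genes with an H3K4me1 promoter in the vehicle list only numbered 1314 in place of 2150.

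H3K9me3, a mark of silent chromatin, was listed at the promoters of ZSCAN22, TRIM28, ZNF584, CHMP2A and SUMF2 with osimertinib and not with vehicle. TRIM28 codes for a corepressor that zinc finger proteins bring to DNA, and its region (chromosome 19, 58543217 to 58545216) ranked 2 of 2073. The strongest promoters with vehicle only belonged to ROCK1P1, DUX4, DUX4L15, BIRC8 and ZNF606. The regions of ZSCAN22 and ZNF606 lay within 3 kb of a region of the other list. The 2 H3K9me3 lists differed in make-up. The strongest region lay between genes near EMB with vehicle and at the ZSCAN22 promoter with osimertinib. The lowest signal was 0.866 with vehicle and 0.0053 with osimertinib, though the scale may differ. Promoters listed with osimertinib only, such as that of TRIM28, may thus reflect how the lists were made. Genes named ZNF with an H3K9me3 promoter region numbered 138 with vehicle and 166 with osimertinib, of which 99 were in both lists. EGFR had 7 regions with vehicle, of which 1 lay within 3 kb of a start (chromosome 7, 55105135 to 55107134), and 0 with osimertinib. That promoter region ranked 2504 of 2749, beyond the 2073 regions of the osimertinib list. Chromosome 7, which carries EGFR, held 11.8% of the regions in each H3K9me3 list. Apart from EGFR, none of the focus genes had an H3K9me3 region in either list.

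The ZNF genes stood at percentile 78.2 for H3K9me3, with 39 in the vehicle list only and 67 in the osimertinib list only. ZNF584, ZNF497, ZNF718 and ZNF891 were the strongest with osimertinib only. Of the 20 other lists, TRIM28 of the lysine methylation list, ETV1 of the EGFR-MAPK list and EGFR of the receptor list were the only genes with an H3K9me3 promoter region. Chromosome 19 held 33.9% of the vehicle regions (32.1 to 35.7) and 43.3% of the osimertinib regions (41.2 to 45.5). This difference too may reflect how the lists were made. H3K9me3 promoter regions were listed for 456 genes with vehicle, 517 with osimertinib and 225 in both, a log2 ratio of 0.18 (-0.0033 to 0.37). The vehicle regions overlapped an osimertinib region for 26.0% (24.4 to 27.7), and the reverse share was 34.5% (32.5 to 36.6), with rotation means of 2.18% and 2.84%. Counting any region assigned to a gene, 752 genes were in the vehicle list only and 468 in the osimertinib list only, in place of 231 and 292 with promoter regions.

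KDM1A itself had the strongest region of the KDM1A library with vehicle. Its own promoter (chromosome 1, 23018781 to 23020780 with vehicle) ranked 1 of 4731 with vehicle and 2 of 8882 with osimertinib. EEF1A1, a translation elongation factor gene, ranked 3 with vehicle and had no region with osimertinib. CALM2, a calmodulin gene, ranked 1 with osimertinib and had no region with vehicle. A few regions stood far above the rest with vehicle, where the signal was 29.4 at rank 9 and 3.07 at rank 11. The median of that list was 0.991. Whether such regions show KDM1A held there could not be told from these data. EGFR had a KDM1A promoter region with osimertinib only, ranked 7568 of 8882, and none of the other focus genes apart from KDM1A had a KDM1A region. Chromosome 7, which carries EGFR, held 9.32% of the KDM1A regions with vehicle and 11.3% with osimertinib, against 5.08% and 5.25% of the H3K4me3 regions. The EGFR region may thus be part of a wider excess on that chromosome. Promoter regions were listed for 723 genes with vehicle, 1178 with osimertinib and 124 in both, a log2 ratio of 0.70 (0.57 to 0.84).

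Within the KDM1A gene, both lists held 6 regions assigned to it, of which 3 lay at annotated transcript starts and 3 on exons 2, 9 and 11 of 19. Regions assigned to MIR4419A and MIR3115 lay between them. With vehicle these 8 regions ranked between 1 and 9. With osimertinib the promoter region and the regions on exon 2 and exon 9 ranked 2, 7 and 9, and the region on exon 11 ranked 130.

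**Figure D4:**
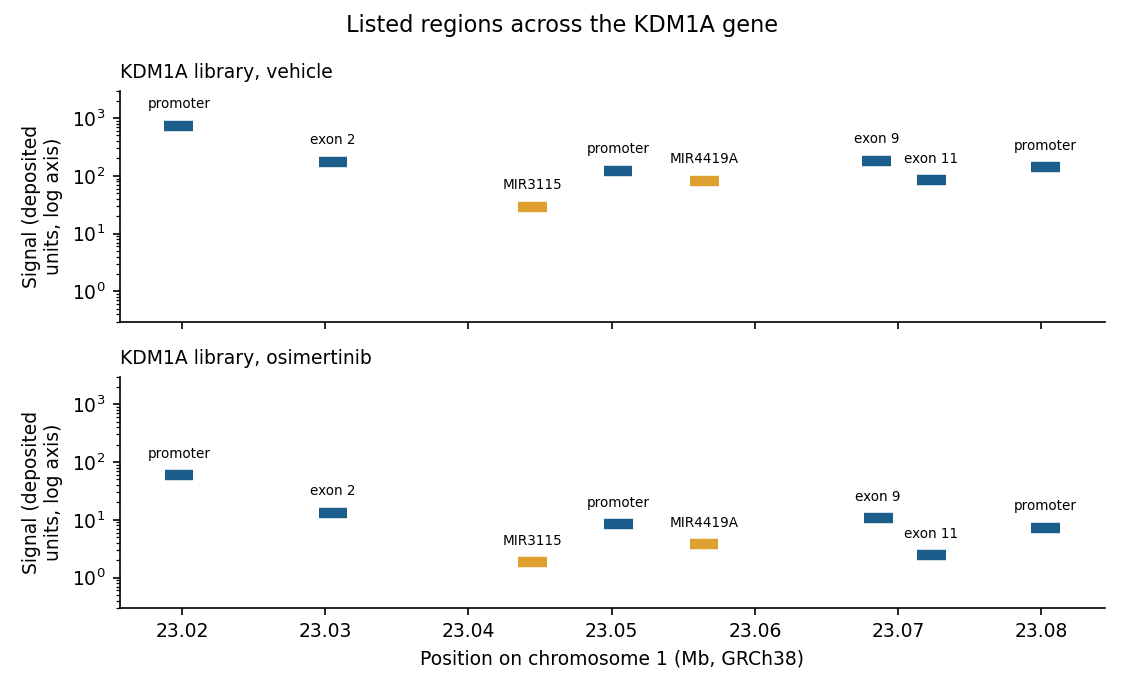
Position on chromosome 1 (horizontal axis, Mb) and deposited signal (vertical axis, log scale) of each region listed across the KDM1A gene in the KDM1A libraries, vehicle above and osimertinib beneath, with 1 library each. Blue segments were assigned to KDM1A and orange ones to a microRNA gene, and the promoter region at the left has the highest signal of the regions shown for each treatment.

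KDM1A promoter regions with osimertinib only had their highest signals at CALM2, H3F3B, CALM2P2, CALM2P3 and H2AFZP2, of which the last 3 are pseudogenes. With vehicle only they were EEF1A1, ZNF329, DDX11L16, MTND5P18 and ZYG11AP1. Among the fixed lists, HSD17B12 and ACSL4 of fatty acid synthesis had a KDM1A promoter region with osimertinib only and PFKM of glycolysis with vehicle only, while 0 genes of fatty acid oxidation or cholesterol synthesis had one. These regions were weak within their lists: HSD17B12 and ACSL4 ranked 6231 and 8684 of 8882, and PFKM 4288 of 4731. SPRY2 and ETV1 of the EGFR-MAPK list, ranked 11 and 4661 of 8882, were in the osimertinib list only. EREG, ranked 2492 of 4731, was in the vehicle list only and EPHA4 in both. MET, ranked 2583 of 4731, was in the vehicle list only. In the lysine methylation list KDM5B, KMT2C and RCOR1 were in the osimertinib list only and RCOR3 in the vehicle list only, at percentile 60.4. CDK1, CYCS, CLDN1 and ESRP1 were in the osimertinib list only and FN1 and COL1A2 in the vehicle list only. Genes named ZNF numbered 10 with vehicle only, 25 with osimertinib only and 8 in both, at percentile 70.2. ZNF329 and ZNF704 were among the strongest with vehicle only, and ZNF551 and ZNF667 with osimertinib only.

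The first 50 Mb of chromosome 5 held 12.7% of the KDM1A regions with vehicle (11.8 to 13.7) and 22.9% with osimertinib (22.1 to 23.8), against 0.766% and 0.820% of the H3K4me3 regions. The cadherin genes CDH18, CDH12 and CDH9 and the catenin gene CTNND2 lie there. CDH18 had 16 KDM1A regions with vehicle and 83 with osimertinib, CTNND2 14 and 61, CDH9 8 and 41, and CDH12 16 and 39. The rise was not confined to that stretch. On other chromosomes CNTN5 had 10 and 43, ALCAM 9 and 41, and CBLB 8 and 35, while GABRB1 had 9 and 9. H3K9me3 was listed in the same stretch for 13.4% of its vehicle regions (12.1 to 14.7) and 6.08% of its osimertinib regions (5.09 to 7.19). The log2 ratio of KDM1A region numbers was 0.91 (0.86 to 0.96), and 0.73 without that stretch.

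**Figure D5:**
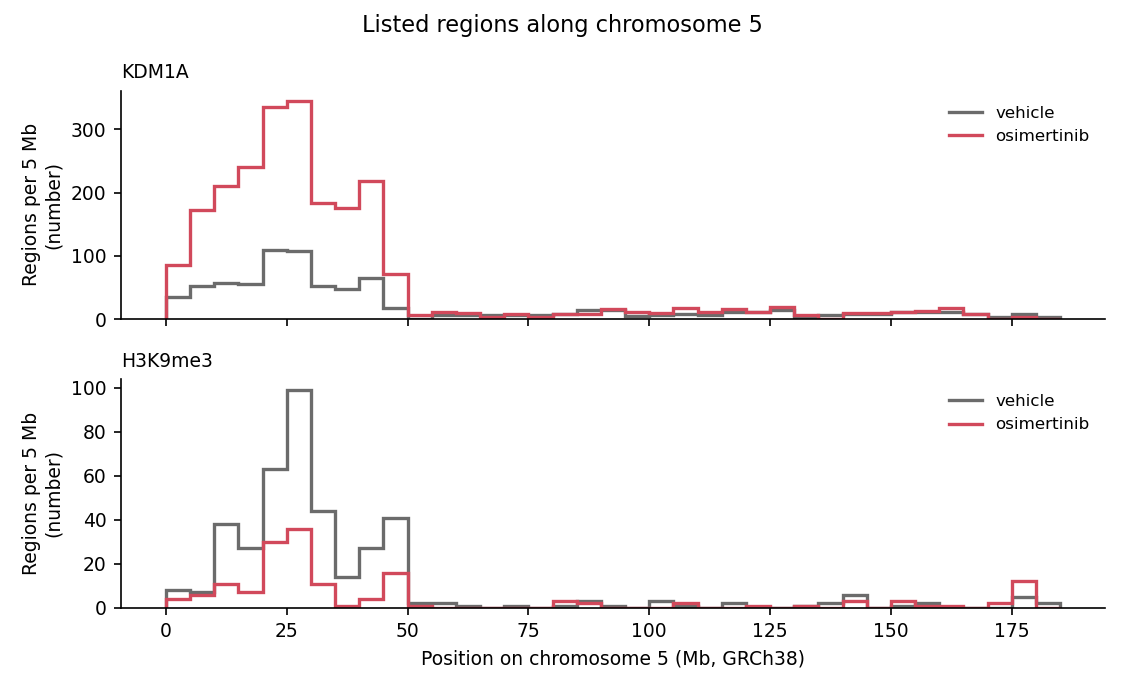
Number of listed regions per 5 Mb (vertical axis) along chromosome 5 (horizontal axis, Mb) for KDM1A (above) and H3K9me3 (beneath), with vehicle in grey and osimertinib in red, 1 library each. In both panels the regions crowd in the first 50 Mb, which hold 2037 KDM1A regions with osimertinib and 601 with vehicle.

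KDM1A regions overlapped between treatments for 9.43% of the vehicle list (8.61 to 10.3) and 5.07% of the osimertinib list (4.62 to 5.54), with rotation means of 1.95% and 1.06%. Requiring an overlap of 1000 bp lowered the vehicle share to 6.13%. With equal numbers of strongest regions, 576 genes had a KDM1A promoter in the osimertinib list only and 638 in the vehicle list only, in place of 1054 and 599, so the excess with osimertinib did not hold in lists of equal length.

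KDM1A was next set against the marks of the same treatment, and such overlap does not measure action of the enzyme on a mark. Few KDM1A regions overlapped any of the marks. With vehicle 1.33% lay on an H3K4me1 region (1.02 to 1.70), 0.803% on H3K4me3 (0.569 to 1.10) and 2.35% on H3K9me3 (1.93 to 2.82), where rotation gave means of 1.26%, 1.40% and 0.467%. With osimertinib the shares were 2.77% (2.44 to 3.13), 2.42% (2.11 to 2.76) and 1.95% (1.67 to 2.26), with rotation means of 0.895%, 1.54% and 0.320%. Vehicle KDM1A regions that were also in the osimertinib list overlapped H3K9me3 for 12.1% (9.23 to 15.5), and those in the vehicle list only for 1.33% (1.01 to 1.72). The same shares with osimertinib were 5.56% (3.63 to 8.09) and 1.76% (1.49 to 2.06). These splits were not run without the first 50 Mb of chromosome 5, where KDM1A and H3K9me3 regions both crowded. Without it the shared part of the vehicle KDM1A list fell from 9.43% to 6.46%. The splits may thus reflect that stretch. Osimertinib KDM1A regions overlapped H3K9me3 regions of the vehicle list for 5.53% (5.06 to 6.02), above the 1.95% within osimertinib. The first 50 Mb of chromosome 5 held 22.9% of these KDM1A regions and 13.4% of the vehicle H3K9me3 regions, against 6.08% of the osimertinib H3K9me3 regions. The vehicle H3K9me3 list was also longer, with 2749 regions against 2073. This comparison was not run without that stretch, so it may reflect crowding there. With equal numbers of regions the vehicle share on H3K4me1 was 0.761%, and the shares on H3K9me3 were 1.84% with vehicle and 2.62% with osimertinib, the other order.

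The KDM1A region of EGFR with osimertinib (chromosome 7, 55106559 to 55108558) lay inside the gene, away from the H3K4me3 region at its first start (55018893 to 55020892 with vehicle). It overlapped H3K4me1 regions of both lists (55107345 to 55109344 with vehicle) and the H3K9me3 region of the vehicle list (55105135 to 55107134). At CYCS the KDM1A and H3K4me3 regions, both with osimertinib only, overlapped. Other genes were matched by gene and not by site. Of genes with KDM1A at a promoter with osimertinib only and the mark at a promoter, the KDM1A region lay within 1 kb of a promoter region with the mark for 59.6% with H3K4me1 (48.6 to 69.8), 41.5% with H3K4me3 (35.5 to 47.6) and 77.8% with H3K9me3 (67.2 to 86.3). Among the 89 genes with KDM1A at the promoter with osimertinib only and an H3K4me1 promoter region, H3K4me1 was in the osimertinib list only for 32.6% (23.0 to 43.3) and in the vehicle list only for 28.1% (19.1 to 38.6). Among the 3312 genes with H3K4me1 and no KDM1A promoter region these shares were 15.7% (14.5 to 17.0) and 63.4% (61.8 to 65.1), and among 37 genes with KDM1A with vehicle only 27% (13.8 to 44.1) and 51.4% (34.4 to 68.1). For H3K4me3 they were 17.8% (13.4 to 22.9) and 21.5% (16.7 to 26.9) of 270 genes with KDM1A, and 17.6% (16.8 to 18.4) and 27.6% (26.7 to 28.6) of 9413 without. For H3K9me3 they were 18.5% (10.8 to 28.7) and 37.0% (26.6 to 48.5) of 81 genes, 42.0% (38.1 to 46.0) and 29.9% (26.4 to 33.7) of 628 without, and 50% (29.1 to 70.9) and 29.2% (12.6 to 51.1) of 24 with KDM1A with vehicle only. Genes are not replicates. With equal numbers of regions the H3K4me1 shares at genes with KDM1A were 52.6% and 15.8%, and with promoters within 1 kb they were 21.7% and 32.6%, so their order depended on how promoters were defined. For H3K9me3 the 37.0% became 24.4% with equal numbers. The shares of KDM1A genes with each mark were not run without the first 50 Mb of chromosome 5.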

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

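The runs without the first 50 Mb of chromosome 5, those without regions on pseudogenes, both alternatives for KDM1A genes against the marks, and the gene list runs that counted a region of the other list within 1 kb as in both were chosen after the data were seen. Of 271 alternative values for 69 results, 208 stayed within the counting interval, within 1.5 times the count or on the same side of the 5th and 95th percentiles, and 63 did not. No log2 ratio of region numbers or promoter share difference changed sign. Of 51 alternatives for 14 comparisons of an osimertinib value with a vehicle value, a set of comparisons chosen after the data were seen, 5 turned the order round. Merging regions within 1 kb, leaving out chromosome Y, leaving out regions on pseudogenes, and dropping promoter genes within 1 kb of the other list left each result they were run on in that range. The planned stricter significance and fold enrichment were not run, since no column used here holds either. Gene assignment from a reference annotation was not run, and the share of covered length equals the share of regions, since all are listed as 2 kb wide. That width may not be the true extent, a doubt that applies to all region numbers and overlaps. Regions with the width column repeated made up 5.73% of the KDM1A list with vehicle and 13.4% with osimertinib, and 17.5% and 26.1% of the H3K4me3 lists. No paired analysis was possible because each group has 1 library. Read depth is unknown and limits every value. The cause was not tested for any change given here, except that fewer or more regions or genes entered by construction.

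An overlap of 1000 bp lowered the shared part of the vehicle lists to 6.13% for KDM1A, 17.7% for H3K4me1, 46.4% for H3K4me3 and 17.0% for H3K9me3, and of the osimertinib lists to 3.27%, 26.6%, 40.6% and 22.5%. Counting regions within 1 kb raised the vehicle shares to 12.1%, 32.6%, 67.6% and 32.8% and the osimertinib shares to 6.70%, 48.3%, 58.5% and 42.3%. It raised KDM1A on H3K4me1 and H3K4me3 with osimertinib to 3.30% and 3.15%, and on H3K9me3 to 3.02% with vehicle and 2.59% with osimertinib.

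With equal numbers of the strongest regions, the vehicle shares were 6.85%, 33.0%, 58.3% and 32.7%, and the osimertinib shares 6.89% for KDM1A, 33.1% for H3K4me1 and 58.0% for H3K4me3. KDM1A promoter genes with osimertinib only numbered 576 and with vehicle only 638, in place of 1054 and 599. H3K4me1 promoter genes with vehicle only numbered 1314. The promoter share with osimertinib minus vehicle was -13.1 points for H3K4me3 and 6.80 for H3K9me3. KDM1A on H3K4me1 with vehicle was 0.761%, on H3K4me3 with osimertinib 2.01%, and on H3K9me3 1.84% with vehicle and 2.62% with osimertinib, in place of 2.35% and 1.95%. The ZNF list for H3K4me3 moved to percentile 85.9. Of genes with KDM1A at the promoter with osimertinib only, H3K4me1 was with osimertinib only for 52.6% and with vehicle only for 15.8%, and H3K9me3 with vehicle only for 24.4%.

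With promoters within 1 kb, KDM1A promoter genes numbered 646 with osimertinib only and 377 with vehicle only, the promoter share difference was -13.3 points for H3K4me1 and -18.3 for H3K4me3, and H3K4me1 was with osimertinib only for 21.7% and with vehicle only for 32.6% of the genes with KDM1A, in place of 32.6% and 28.1%. Counting any assigned region, the numbers with osimertinib only and vehicle only were 2597 and 2094 for KDM1A and 468 and 752 for H3K9me3, the latter in place of 292 and 231, and 954 with osimertinib only for H3K4me1. Then the ZNF list for KDM1A stood at percentile 95.7, lysine methylation genes for H3K4me1 at 3.58, cell cycle genes for H3K4me3 at 3.57 and epithelial genes at 29.4, and without matching the epithelial list stood at 36.5. It stood at 37.4 when a region of the other list within 1 kb counted as in both. The TCA cycle list stayed under the 5th percentile for H3K4me3 in the 4 alternatives run on it. Without the first 50 Mb of chromosome 5 the log2 ratio of region numbers was 0.73 for KDM1A and -0.29 for H3K9me3. The shared part was 6.46% and 3.90% of the vehicle and osimertinib KDM1A lists and 29.1% of the H3K9me3 vehicle list. KDM1A on H3K4me1 and H3K4me3 with osimertinib was then 3.27% and 3.02%, and on H3K9me3 1.69% with vehicle and 1.99% with osimertinib, again the other order.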

Other observations

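The genes and regions in the first 2 paragraphs, and the tests on pseudogenes, on the KDM1A vehicle list, on genes sorted by vehicle signal and on regions within 3 kb, were chosen after the results were seen, and the other tests before. The strongest H3K4me3 regions with vehicle lay at the promoters of MALAT1, TXNRD1, ELF3, NEAT1 and KRT8, ranked 1 to 5 of 11621. MALAT1 and NEAT1 make long noncoding RNAs, TXNRD1 codes for thioredoxin reductase, and ELF3 and KRT8 are epithelial genes. With osimertinib ACTG1 ranked 1, MALAT1 2, IER2 3, KRT8 7, TXNRD1 12 and MYC 15 of 13285. The genes with the most H3K4me1 regions with vehicle were BCAR3, with 43 regions with vehicle and 42 with osimertinib, TNS3 with 37 and 29, and PVT1, next to MYC, with 31 and 40. Regions assigned to ZMIZ1 numbered 22 and 5, and those assigned to ASAP1 18 and 32.

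The strongest H3K4me1 region in both lists, and the strongest H3K9me3 region with vehicle, overlapped each other between genes near EMB (chromosome 5, 49657782 to 49659781 for H3K4me1 with vehicle). The osimertinib KDM1A list held a region there too, ranked 13, so this site was not particular to a mark. With vehicle, regions between genes near ANKRD26P1 and CWH43 were also among the strongest of both marks. Whether sites with high background were filtered out is not known. Of the H3K9me3 regions, 4.91% with vehicle (4.13 to 5.79) and 14.5% with osimertinib (13.0 to 16.1) overlapped an H3K4me3 region of the same treatment. The vehicle H3K9me3 regions overlapped an osimertinib H3K4me3 region for 15.1% (13.7 to 16.5).

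The strongest KDM1A regions lay on KDM1A itself, on EEF1A1 with vehicle, and on CALM2 and processed copies such as CALM2P2 and CALM2P3 with osimertinib. KDM1A held at the strongest active promoters was argued against, since 30% of the 50 strongest osimertinib regions (17.9 to 44.6) lay on an H3K4me3 region, under the share of at least 50% set beforehand, although this is above the 2.42% of all KDM1A regions. Of the 50 strongest, 32.0% (19.5 to 46.7) lay on a pseudogene against 2.45% of the rest (2.13 to 2.79), which restates the pattern that prompted the test and does not support DNA copied from spliced RNA as its source. The vehicle list, where pseudogenes had not prompted it, gave 4% (0.488 to 13.7) against 2.97%. Copied DNA and KDM1A held at these places cannot be told apart here, and other sources of such regions were not examined. The pseudogene shares do not bear on the regions on exons of KDM1A, which were in both lists and stay open.

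KDM1A regions crowded on the first 50 Mb of chromosome 5 in both treatments. A response to osimertinib alone was argued against, since the vehicle list already held 12.7% there (11.8 to 13.7) against 0.766% of H3K4me3 regions. Extra DNA copies could raise the background there, and H3K9me3 with vehicle was crowded too, at 13.4%, with 20.7% of its weaker part there and 6.04% of its stronger part. The weaker part of the osimertinib KDM1A list held 17.3% there (16.2 to 18.4) and the stronger part 28.6% (27.2 to 29.9). The vehicle KDM1A list went the same way, with 6.93% (5.94 to 8.03) and 18.5% (16.9 to 20.1). Such an osimertinib result had been set beforehand as evidence against extra copies. That choice was judged wrong after the result was seen, since extra copies can raise the signal of such regions as well as their number. The crowding of both targets ended near the same place. From 45 to 50 Mb and from 50 to 55 Mb, KDM1A with osimertinib had 72 and 7 regions. H3K9me3 with vehicle had 41 and 2, and H3K4me3 with vehicle 0 and 3. Extra copies could give such a shared edge, which does not exclude KDM1A held there. The 2 cannot be told apart, because the parts of the H3K9me3 and KDM1A lists went opposite ways and no copy number or IgG values were used here.

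H3K4me3 promoters such as ACACA and FH were absent from the osimertinib list. Assignment of their regions to another gene was argued against as the main cause, since 13.7% of the absent genes (12.5 to 15.1) had an osimertinib region within 1 kb of their vehicle promoter region, and 20.7% (19.2 to 22.2) within 3 kb. An absence of listed promoters centred on EGFR-MAPK genes was not seen, since that list stood at percentile 64.1 for H3K4me3, and 74.3 without matching. The score counts only presence in a list, and 16 of the 20 genes were in both. A weaker mark at those genes would not show, so such a loss stays open. Of the 1620 genes weakest by vehicle signal 64.9% were absent (62.5 to 67.2) against 6.67% of the 1619 strongest (5.5 to 8.0), but weak regions leave a second list more often under any cause, and KDM1A, with a longer osimertinib list, showed such a fall too, from 93.8% to 60%. Weaker enrichment in the osimertinib library and a treatment effect cannot be told apart without a replicate.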
